A study of Homo sapiens with 2 samples.

How the data were processed

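Total RNA from human cells labelled SH-SY5Y, a neuroblastoma line, was sequenced in 2 libraries, 1 from cells stably carrying an empty vector and 1 from cells stably carrying an MZF1-AS1 expression vector. Per the labels, stable lines were selected with neomycin, libraries were made with the Illumina TruSeq RNA kit, and 100 bp paired-end reads came from an Illumina HiSeq X instrument. Per the submitters' processing notes, the genome build was hg38 and the tools named are Bowtie2 2.0.6 and TopHat2 2.0.9. Per the labels' design text, reads per gene were counted with HTSeq 0.6.0, and its overlap and strand settings are not given in the sources used here. The kit does not mark strand, so reads of MZF1-AS1 and of the overlapping sense gene MZF1 cannot be told apart in the bases both share.

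The deposited values are a normalised signal per gene, not raw reads: both files list 27377 Ensembl genes, and 1 read is worth 1.0661 in the empty-vector file and 0.93800 in the MZF1-AS1 file. How the authors scaled the values is not given in the sources used here. Dividing by these steps gave whole reads for 100% of the values in each file, within 0.05 of a read, with totals of 17994537 reads in the empty-vector library and 20903334 in the MZF1-AS1 library. The fewest reads over both libraries was 2, so a gene with less than that has no row. TMM factors computed with edgeR 4.0.16 on the recovered reads gave steps of 1.0661 and 0.93800 as well, so the deposited scaling equals a TMM scaling. The design fixed before the data were examined had assumed raw counts scaled by TMM. Ratios of the deposited values were therefore used for every main value.

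With 1 library per group there is no replicate check, no test of the conditions and no p-value. Each ratio carries an exact 95% interval, obtained from the Clopper-Pearson interval of the MZF1-AS1 share of a gene's reads, which covers counting error only. Sequencing reads without molecular identifiers are not independent molecules, so these intervals are lower limits of the error. A gene was counted as higher or lower when its ratio passed 1.5-fold and the interval excluded 1, among genes with a mean of at least 1 CPM over both libraries (14674 genes). CPM here is the deposited value scaled by the mean total of both files, 1 CPM being a value of 19.4. A library at 0 reads was set to 3 counts. The fold then depends on that floor, and the lower limit of the exact interval is the bound that the reads give. A gene at 1 CPM had 18.2 reads in the empty-vector library and 20.7 in the MZF1-AS1 library.

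Simulated libraries with these levels and depths, 14674 genes and 200 altered genes, were used to test the rule. With counting error alone it recovered 46.3% of 1.5-fold, 89.6% of 2-fold and 100% of 4-fold alterations, 95.7% of intervals held the true ratio, and 97 unaltered genes passed. With an extra variation of 5% between cultures 129 unaltered genes passed, with 10% it was 416 and with 20% 2556, and the intervals that held the true ratio fell to 78.0%, 59.8% and 42.3%.

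The 26 gene lists were written before the data were examined. They cover proline metabolism, serine, glycine and one-carbon metabolism, the integrated stress response, E2F and G1/S targets, G2/M genes, the PARP family, MYC and MYCN targets, adrenergic and mesenchymal neuroblastoma genes, neuronal differentiation, glycolysis, hypoxia, matrix, adhesion and invasion, cholesterol synthesis, interferon response, p53 targets, the unfolded protein response, immediate-early genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, ribosomal proteins, replication histones, Schwann and glial markers, epithelial markers, blood markers and neighbours of MZF1. For each, the median log2 ratio of members above the floor, less that of all 14674 genes, is given with a 95% range over 200 Poisson redraws of the reads. This difference does not depend on library scaling. Its percentile among 10000 random lists of equal size, matched on mean expression in 25 bins, describes these libraries and is not a p-value. A further pair of lists, 88 genes common on clinical cancer panels and 34 genes of drug response, was written after the data had been seen.

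Symbols came from the supplied table of Ensembl names and GENCODE 29, which held 26874 of the 27377 identifiers. The identifiers outside it carried 0.100% of the deposited signal. Coordinates are those of GENCODE 29 on hg38. The genes named are MZF1-AS1 and MZF1, every proline-list member above the floor, up to 3 highest and 3 lowest members past 1.5-fold of each other list, and the 12 highest and 12 lowest protein-coding genes with a mean of at least 5 CPM, leaving out XIST, Y-linked and mitochondrially encoded genes. Other genes are named as examples chosen after their values were seen, and this is said where they appear. Some genes that the rule names are not reported here.

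Alternatives were total count, DESeq2 1.42.0 and upper-quartile scaling, scaling without the 20 most abundant genes, the deeper library thinned at random to 86.1% of its reads, a floor of 5 CPM or none, thresholds of 2-fold and 4-fold, the threshold applied to the interval bound, protein-coding genes only, an edgeR prior count of 2, means in place of medians and unmatched random lists. Alternatives added after seeing the data were TMM on the recovered reads, leaving out the panel genes, and random lists matched also on exonic length and GC content. Other steps used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.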

Results

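The transcriptome of cells labelled SH-SY5Y and carrying an MZF1-AS1 vector was set against that of cells carrying the empty vector, with 1 RNA-seq library per group. The empty-vector library held 17994537 reads assigned to genes and the MZF1-AS1 library 20903334. The question was how these cells respond to stable overexpression of MZF1-AS1, a long non-coding RNA transcribed antisense to the zinc finger gene MZF1. Because no group has a replicate, every difference below is one between 2 libraries, and intervals cover counting error only.

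The transfected gene was checked first. MZF1-AS1 (ENSG00000267858, chromosome 19, 58559129 to 58574797, plus strand, hg38) had a normalised read count of 58.6 in the empty-vector library and 11551 in the MZF1-AS1 library, from 55 and 12315 reads. That is a 197-fold higher level (95% counting interval 151 to 262), or 7.62 on the log2 scale. The sense gene MZF1 (ENSG00000099326, 58561931 to 58573575, minus strand) had normalised counts of 475 and 531, a ratio of 1.12 (0.985 to 1.27) that was not distinguishable from 1 at this depth. The annotated exons of MZF1-AS1 cover 2968 bases, of which 1181 also lie in exons of MZF1, so reads from that part may be assigned to either gene or to neither. MZF1 had 446 and 566 reads, so at most 566 vector-derived reads can have gone to it, beside 12315 for MZF1-AS1. Both levels stay uncertain, because the shared reads within the 566 and those assigned to neither gene are not known.

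**Figure D1:**
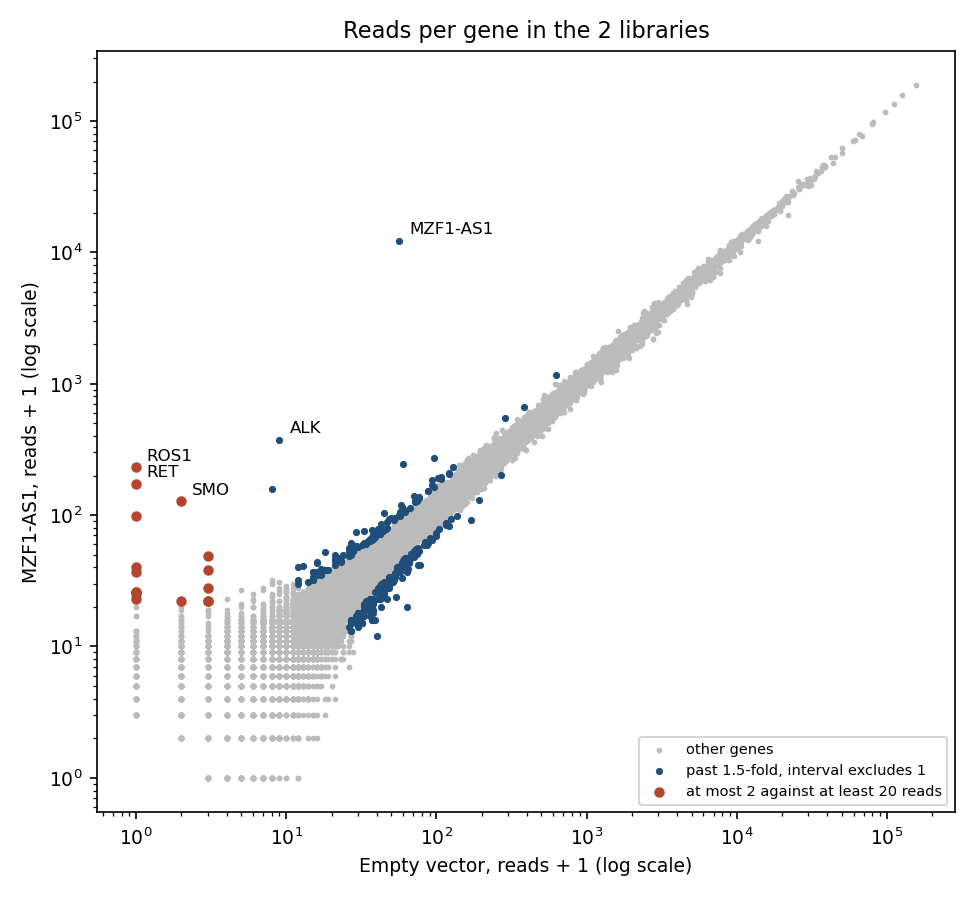
Reads per gene plus 1 in the empty-vector library (horizontal, log scale) and in the MZF1-AS1 library (vertical, log scale), 1 point per gene. Blue points passed 1.5-fold with an interval excluding 1, and red points are the 16 genes with at most 2 reads in the empty-vector library and at least 20 in the MZF1-AS1 library; MZF1-AS1 stands alone at 55 against 12315 reads.

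Apart from the transfected gene, the libraries were close. Among 14674 genes above the floor, 117 were at least 1.5-fold higher in the MZF1-AS1 library, MZF1-AS1 included, and 151 were at least 1.5-fold lower, together 1.83% of the genes. Among the 4670 genes above 50 CPM, the log2 ratio had a standard deviation across genes of 0.149, and outside MZF1-AS1 and the panel genes the highest log2 ratio was 0.45. On the lower side PLK1, at 129 CPM and named after its value was seen, had a log2 ratio of -0.50. In simulated libraries 97 unaltered genes passed the same rule from counting error alone, 129 with 5% variation between cultures and 416 with 10%, against 268 genes here. Simulated intervals held the true ratio for 78.0% of genes at 5% and 59.8% at 10%. Here 20.9% of genes had an interval that excluded 1, so by that share the 5% setting lies nearer. Variation between cultures cannot be measured with 1 library per group. Total count scaling shifted the split to 96 higher and 190 lower, and a floor of 5 CPM turned it to 24 higher and 8 lower.

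The 12 highest protein-coding genes were led by genes of receptor tyrosine kinases. ROS1 had 0 reads in the empty-vector library and 232 in the MZF1-AS1 library. Against a floor of 3 counts it was 68.0-fold higher, with an exact interval from 54.9 upward. ALK had normalised counts of 8.53 and 352, 41.2-fold higher (20.7 to 96.2). DDR2, a collagen receptor kinase, was 3.62-fold higher (2.72 to 4.90) and FGFR2, a fibroblast growth factor receptor, 2.51-fold higher (1.98 to 3.21). ROS1 belongs to 16 genes with at most 2 reads in the empty-vector library and at least 20 in the MZF1-AS1 library, of which 9 do not encode a kinase and 4 are pseudogenes, 3 of them of MAP2K1, GNAQ and BRAF. ROS1, ALK, DDR2 and FGFR2 all belong to the cancer-panel list, which was written after the data had been seen, and without both panel lists and their pseudogenes 107 genes were higher and 151 lower. Reads from a DNA capture library for cancer and drug-response genes stay an open candidate source for them, as described under Other observations. The AP-1 gene FOSB was 1.75-fold higher (1.30 to 2.36), at 74.6 and 130. The remaining genes of the 12 were FAM86C1P, HYI, FAM111B, SV2B, FAM131C and the interferon-induced IFIT2 and OASL, with ratios from 1.57 to 1.73. Of these, FAM111B rested on the most reads, with 628 and 1167 (1.64-fold, 1.48 to 1.80).

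The 12 lowest protein-coding genes were less extreme. CNIH3, an auxiliary subunit gene of AMPA receptors, was 2.13-fold lower (1.64 to 2.79), at normalised counts of 180 and 84.4. ALOX15, a lipoxygenase gene, was 1.69-fold lower (1.35 to 2.13), and GLTPD2, SEPSECS, ZNF443 and CPEB1 were between 1.52-fold and 1.68-fold lower, although CPEB1 missed 1.5-fold after thinning. A further 5, CHIC2, TLX3, PIF1, NEIL3 and ZNF862, lay below 1 by less than 1.5-fold, but CHIC2 and TLX3 passed 1.5-fold under total count scaling and after thinning, and NEIL3 after thinning. PIF1, a DNA helicase gene, and NEIL3, a DNA glycosylase gene, were 1.44-fold lower (1.26 to 1.65, and 1.12 to 1.85).

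Genes of proline metabolism were examined because the study is known to be about MZF1-AS1 and proline synthesis. None of the 14 members above the floor passed 1.5-fold, and their ratios ran from 0.908 to 1.16. ALDH18A1, the pyrroline-5-carboxylate synthase gene at the start of proline synthesis from glutamate, had normalised counts of 3305 and 3445 (ratio 1.04, 0.994 to 1.09). PYCR1, which encodes the mitochondrial enzyme of the last step, had 1439 and 1450 (1.01, 0.936 to 1.08), and PYCR3 had 594 and 539, all with intervals that held 1. Among the members named, the intervals excluded 1 for P4HA1, a collagen prolyl hydroxylase gene (1.16, 1.08 to 1.26), for GLUD1 (1.09, 1.03 to 1.15) and for the glutamine transporter gene SLC1A5 (1.09, 1.02 to 1.17). Over all genes above the floor, 20.9% had an interval that excluded 1, so this does not set these members apart. SLC38A2, PEPD and P4HA2 had ratios of 1.02, 1.06 and 1.09, and OAT, PRODH and ALDH4A1 had 0.932, 0.982 and 0.910, each with an interval that held 1. The list median lay 0.04 above that of all genes on the log2 scale (-0.01 to 0.09), at percentile 82.4 of matched random lists.

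Cell-cycle genes of different phases differed in opposite directions. All 26 genes of the G2/M list, which act in mitosis, were lower in the MZF1-AS1 library with intervals below 1, although none passed 1.5-fold. Their median lay at -0.28 relative to all genes (-0.32 to -0.27), below all 10000 random lists. Of the 37 E2F and G1/S genes, 30 lay above the median of all genes, 23 with the whole interval above it, and the list median was 0.15 (0.11 to 0.18), at percentile 100. Chosen after the values were seen, the mitotic kinase gene PLK1 was 1.42-fold lower (1.34 to 1.501), BUB1 of the spindle checkpoint 1.37-fold (1.30 to 1.44), CENPF 1.29-fold (1.26 to 1.32) and cyclin B1 (CCNB1) 1.24-fold (1.19 to 1.29). On the G1/S side, cyclin E genes CCNE2 and CCNE1 were 1.49-fold (1.20 to 1.84) and 1.39-fold (1.21 to 1.59) higher, with CCNE2 past 1.5-fold after thinning, E2F1 was 1.23-fold higher (1.15 to 1.33), and the replication genes MCM6 and PCNA were 1.22-fold and 1.21-fold higher. The exceptions with the whole interval below the median of all genes were CCNA2, 1.27-fold lower, and TK1, 1.10-fold lower, also named after their values were seen.

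**Figure D2:**
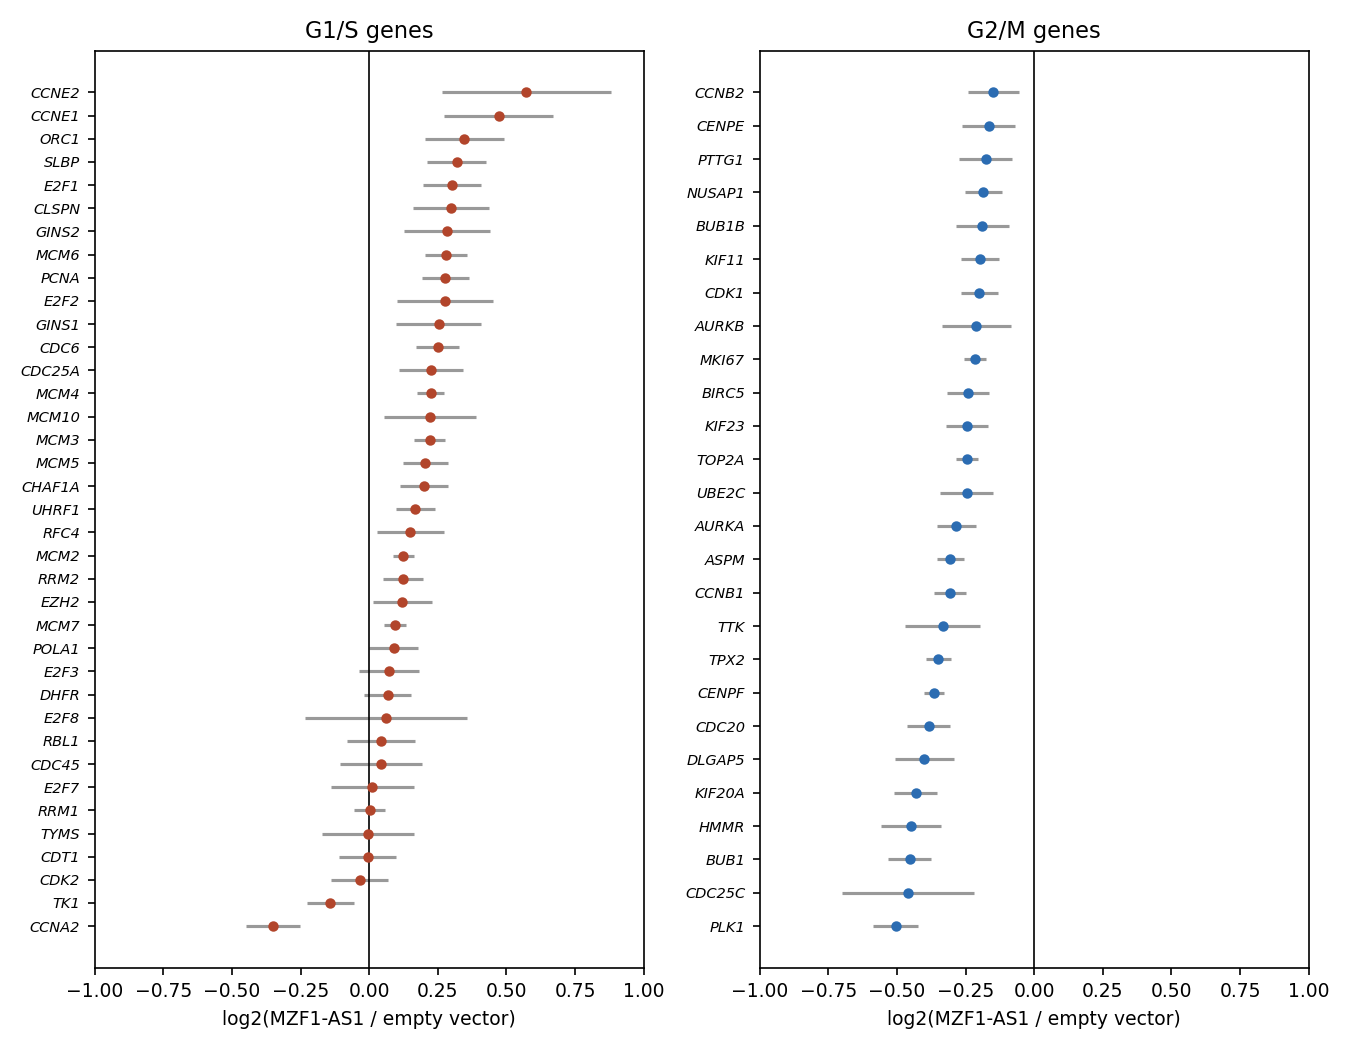
Log2 ratio of the MZF1-AS1 to the empty-vector library for each gene of the G1/S list (left, 37 genes) and of the G2/M list (right, 26 genes), with exact 95% counting intervals as horizontal lines. All 26 G2/M genes lie to the left of 0, and most G1/S genes lie to the right, with CCNA2 as the lowest.

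Other groups tied to growth were also displaced by small amounts. Cholesterol synthesis genes were lower: 22 of 23 lay below the median of all genes, 19 with the whole interval, and the list median was -0.18 (-0.21 to -0.14), at percentile 0 of random lists. As examples chosen after the values were seen, MVD was 1.26-fold lower (1.17 to 1.36), FDPS 1.20-fold (1.12 to 1.29) and LSS 1.19-fold (1.15 to 1.24). Ribosomal protein genes were higher by a median of 0.07 relative to all genes (0.06 to 0.08), with 72 of 75 above that median, at percentile 100 by the median and 89.9 by the mean. The random lists were drawn from all genes above the floor, MZF1-AS1 included. Its log2 ratio of 7.62 weighs on the means of lists that draw it but hardly on their medians. How much of the lower percentile by the mean comes from this was not tested. MYC and MYCN targets had a median of 0.09 (0.07 to 0.11) at percentile 99.99, with NPM1 1.11-fold higher (1.09 to 1.13), and MYC itself had a ratio of 1.05 (1.01 to 1.10), both named after their values were seen. Replication histone genes had a median of -0.13 (-0.27 to -0.02), at percentile 1.61 (2.94 with a floor of 5 CPM), and H2BC17 was the member past 1.5-fold, 1.75-fold lower (1.04 to 2.98) on 40 and 26 reads. These histone values rest on few reads: 21 of the 39 listed genes were above the floor, at a median level of 8.8 CPM.

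The interferon list had a median of 0.09 relative to all genes (0.04 to 0.13), at percentile 99.9, with 4 of 32 members past 1.5-fold: IFI27 (2.64-fold, 1.499 to 4.88, on 17 and 51 reads), IFIT2 (1.69-fold, 1.46 to 1.95), OASL (1.60-fold, 1.29 to 2.00) and, outside the naming rule and named after its value was seen, RIGI (1.51-fold, 1.17 to 1.97). RIGI fell short of 1.5-fold under total count scaling, the prior count and thinning. The integrated stress response list had a median of 0.09 (0.05 to 0.13), at percentile 99.7, with no member past 1.5-fold. Its members ATF3 and SLC7A11, the cystine transporter gene, named after their values were seen, were 1.31-fold (1.21 to 1.41) and 1.28-fold (1.21 to 1.35) higher. Of the 21 members of that list 17 lay above the median of all genes, 6 with the whole interval, and 4 lay below. Hypoxia genes had a median of 0.08 (0.03 to 0.11), at percentile 99.6, but their mean lay at percentile 87.5, inside the central 95%, and the member past 1.5-fold, ANKRD37, was 1.94-fold lower (1.15 to 3.36) on 41 and 24 reads. Immediate-early genes had a median of 0.06 (0.02 to 0.14), at percentile 96.2 (99.3 by the mean and 99.1 with a floor of 5 CPM), with FOSB as the member past 1.5-fold. Nuclear oxidative phosphorylation genes stood at 0.06 (0.02 to 0.07), percentile 99.6 (97.2 by the mean), mitochondrially encoded genes at 0.07 (0.06 to 0.08), percentile 96.8, and glycolysis genes at 0.05 (0.03 to 0.06), percentile 94.98.

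**Figure D3:**
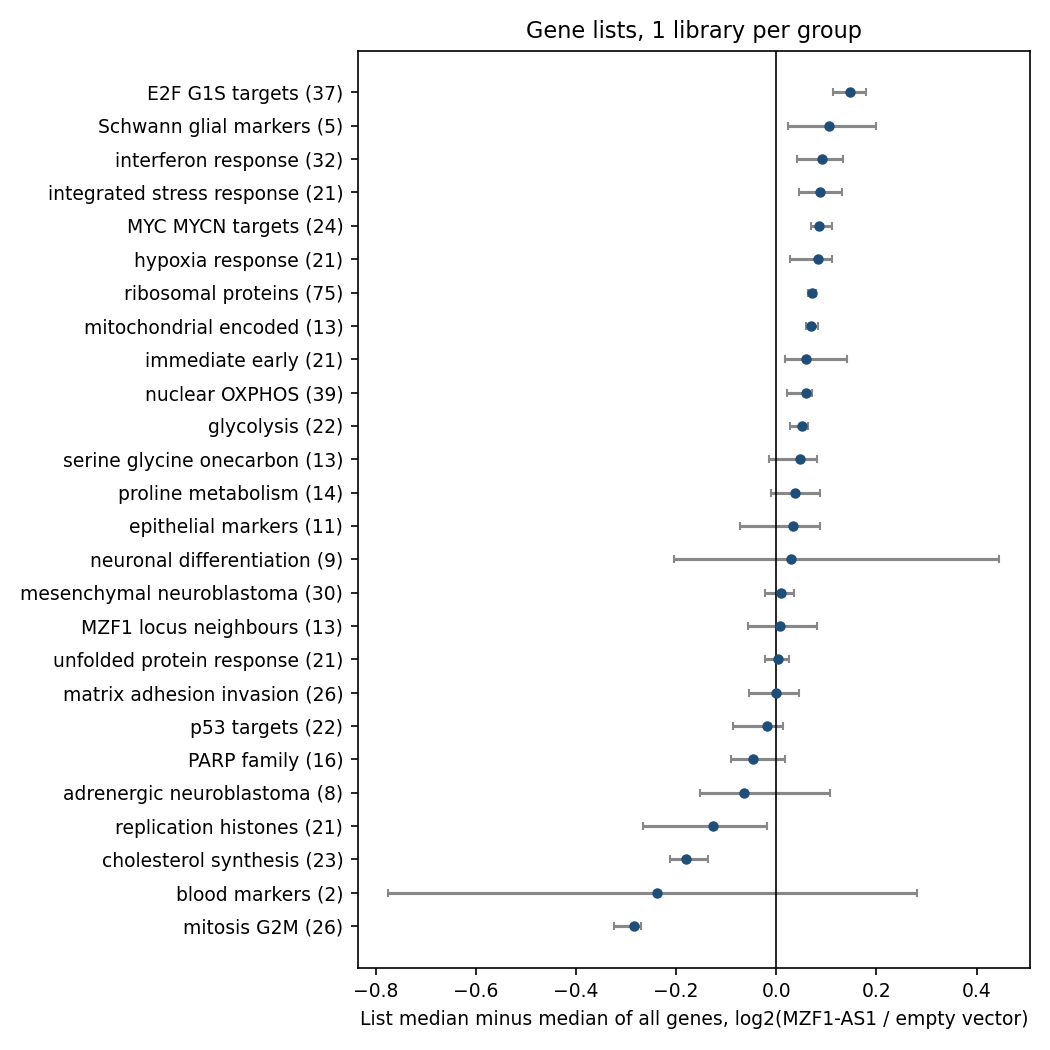
Median log2 ratio of each gene list less that of all 14674 genes (horizontal), with the number of members above the floor in parentheses and bars for the 95% range of Poisson redraws. The G2/M list stands at -0.28 and the cholesterol list at -0.18, and the E2F and G1/S list is the highest at 0.15.

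The remaining pathway lists lay inside the central 95% of random lists. Serine, glycine and one-carbon genes had a median of 0.05 relative to all genes, the PARP family -0.05, p53 targets -0.02, and the unfolded protein response 0.003, at percentiles 88.6, 7.51, 28.5 and 35.9. PARP1, named after its value was seen, had normalised counts of 7664 and 8266 (1.08-fold higher, 1.05 to 1.11). Matrix, adhesion and invasion genes stood at -0.001, percentile 32.0, with PLAU, the urokinase gene, 1.65-fold lower (1.00 to 2.74) on 42 and 29 reads. The 13 neighbours of MZF1 above the floor had a median of 0.007, at percentile 56.3, and none passed 1.5-fold.

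Lists that mark cell types gave levels as well as ratios. Of the 29 adrenergic neuroblastoma genes, 8 were above the floor and 13 had no row in the files used here. ALK and RET were the members past 1.5-fold, and both also belong to the cancer-panel list. RET, one of the 16 genes near silent in the empty-vector library, had 0 and 173 reads. Against a floor of 3 counts it was 50.7-fold higher, with an exact interval from 40.8 upward. The other 6 lay between 0.851 and 1.00 in ratio, and the list median was -0.07 (-0.15 to 0.11), at percentile 17.9. Of the 33 mesenchymal neuroblastoma genes 30 were above the floor, with a median of 0.01 at percentile 54.9 and MEOX1 1.63-fold lower (1.09 to 2.45) on 63 and 44 reads. Of the 26 neuronal differentiation genes 9 were above the floor, with a median of 0.03 (-0.20 to 0.45) at percentile 71.0 and MAP2 1.54-fold higher (1.17 to 2.02). That median was not stable: it was 0.35 at percentile 99.6 with a floor of 5 CPM, 0.30 at percentile 98.9 with no floor and 0.16 after thinning. The floor also sets which members enter it. Of the 16 epithelial markers 11 were above the floor and 3 had no row, with a median of 0.03 at percentile 72.9. The sign of that median was not stable: it was -0.07 at percentile 3.97 with a floor of 5 CPM and -0.007 without panel genes. KRT8, a keratin of simple epithelia named after its value was seen, had normalised counts of 32710 and 31420. Schwann and glial markers (5 genes above the floor) had a median of 0.11 at percentile 92.9, and blood markers (2 genes) had -0.24 at percentile 27.6.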

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

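TMM on the recovered reads, leaving out panel genes and matching on length and GC were chosen after seeing the data. MZF1-AS1 kept its log2 ratio (7.57 to 7.62) and MZF1 its own log2 ratio (0.13 to 0.16) under 5 alternatives each. TMM on the recovered reads gave 117 genes higher and 151 lower, and leaving out panel genes 107 and 151. Total count scaling gave 96 and 190. Counts beyond 1.5 times the main ones came from the floor, the threshold and the restriction to protein-coding genes. They were 24 and 8 with a floor of 5 CPM, 315 and 408 with none, 29 and 50 at 2-fold and 8 and 1 at 4-fold. The interval bound gave 12 and 5, and protein-coding genes gave 65 and 75. Such settings alter the size of the counts by construction, but not which direction leads. Higher genes outnumbered lower ones with a floor of 5 CPM, at 4-fold and by the interval bound, and the cause was not tested.

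Of 155 list medians under alternatives 143 stayed inside their counting range. Without a floor the medians were -0.26 for G2/M genes, 0.111 for MYC and MYCN targets, 0.0751 for glycolysis, 0.0272 for the unfolded protein response, 0.0825 for nuclear oxidative phosphorylation, 0.0934 for mitochondrially encoded and 0.0943 for ribosomal protein genes. Apart from MYC and MYCN targets, all members of these lists with a row were above the floor already. There the median of all genes moved and that of the list did not. Means in place of medians gave 1.30 for the adrenergic list (percentile 99.99), which holds ALK and RET, 0.17 for interferon, 0.0565 for mitochondrially encoded genes (percentile 80.9), 0.0829 for ribosomal proteins (percentile 89.9) and 0.12 for epithelial markers, and percentiles of 99.2 for the E2F and G1/S list and 98.8 for MYC and MYCN targets. Unmatched random lists gave 99.4 for MYC and MYCN targets and 0.01 for cholesterol synthesis. Matching on length and GC gave 71.5 for mitochondrially encoded genes and 99.96 for ribosomal proteins, and a floor of 5 CPM gave 3.97 for epithelial markers. List percentiles also crossed the bounds of the central 95% for hypoxia (87.5) and nuclear oxidative phosphorylation genes (97.2) by the mean, the latter also with length and GC matched (95.3). They crossed for immediate-early genes by the mean (99.3) and with a floor of 5 CPM (99.1), where histones gave 2.94 and the neuronal list 99.6. They crossed without a floor for the neuronal list (98.9) and mitochondrially encoded genes (97.56), and for glycolysis matched on length and GC (98.4). The neuronal median, 0.03, was 0.35 with a floor of 5 CPM, 0.30 without a floor and 0.16 after thinning. Apart from the no-floor medians of lists whose members stayed the same, the cause of these shifts was not tested. Random lists could draw MZF1-AS1, whose log2 ratio of 7.62 raises the mean of any list that holds it. Percentiles by the mean carry that spread.

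With a floor of 5 CPM, members past 1.5-fold were 1 of the adrenergic list and 0 of the mesenchymal, hypoxia, matrix and histone lists. At 2-fold they were 1 of the interferon list and 0 of the mesenchymal, neuronal, hypoxia, matrix, immediate-early and histone lists. Total count scaling gave 2 histone genes. Total count scaling and the prior count gave 3 interferon members, without RIGI. A gene at 1 CPM rested on 18.2 and 20.7 reads.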

Other observations

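All tests in this part were chosen after the results were seen, as were the genes named here other than ROS1, RET, ALK, DDR2, FGFR2 and MZF1-AS1. The gene lists other than the panel lists were written before the data were examined. Differences between the libraries did not follow chromosomes: over the 23 chromosomes with at least 100 genes above the floor, the median log2 ratio relative to all genes ran from -0.02 to 0.03. Mitochondrially encoded genes took 4.15% of reads in the empty-vector library and 4.32% in the MZF1-AS1 library.

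A set of genes was near silent in the empty-vector library and read in the MZF1-AS1 library. There were 16 genes with at most 2 reads in the former and at least 20 in the latter, and 0 genes the other way round. Beside ROS1 and RET they include SMO (1 and 126 reads, ratio 111, 19.5 to 4413), PDGFRA (0 and 97 reads), LRP2 (2 and 48), DSCAM (2 and 37), NOS3 (0 and 25) and the pseudogenes MAP2K1P1 (0 and 39), GNAQP1 (0 and 36) and BRAFP1 (0 and 24). KIT (7 and 158 reads) and ALK (8 and 375) lay just outside that rule, and DDR2 and FGFR2 were higher too. Of the 16 genes 7 encode a kinase, and a 4th pseudogene, AC008267.1 (0 and 25 reads), has no parent gene in its symbol. From the levels of the parent genes MAP2K1, GNAQ and BRAF, 84.0 empty-vector reads were expected at the 3 pseudogenes named after them. There were 0 (upper limit 3.69), so reads there did not follow the parent levels. The 3 were picked by a rule that required few empty-vector reads, so this number does not decide whether parent transcripts were the source. A candidate explanation is reads from a DNA capture library for cancer and drug-response genes, and it stays open: all 14 cancer-panel genes and 13 of 15 drug-response genes with at most 2 empty-vector reads had at least 5 reads in the MZF1-AS1 library, against 11.3% of all such genes, but these lists were written knowing several of those values. Over 74 panel members above the floor, not past 1.5-fold and not seen when the lists were written, the median lay 0.02 above all genes, at percentile 83.4, which decides nothing. The whole lists had medians of 0.05 (percentile 99.8) and 0.03 (percentile 72.9). A transcriptional response to MZF1-AS1 was not tested and stays open.

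Adrenergic neuroblastoma genes were low in both libraries and epithelial markers were abundant. In both libraries, 20.7% of the adrenergic list stood above 1 CPM, against 68.8% of the epithelial list, with KRT8 at 32710 and 31420, KRT18 at 5128 and 4904 and KRT7 at 3423 and 3360 normalised counts, while the adrenergic genes GATA2 (947 and 899) and KLF13 (4124 and 3970) were also read. Depth does not account for this, since a gene at 1 CPM had 18.2 reads in the shallower library. A hypothesis is that cells of an epithelial type are present in both cultures, and the 68.8% goes with it, although the epithelial markers KRT5, KRT19 and ESRP1 had no row. Every gene with a row has at least 2 reads over both libraries, so these may have had fewer, which was not tested. A mesenchymal state of neuroblastoma cells cannot be told apart from it, because 87.9% of the mesenchymal list also stood above 1 CPM and it holds genes that many cultured cells express, such as VIM (3910 and 3969). Whether the cell line label holds for these libraries is therefore in doubt, and it was not tested further.

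The opposite displacement of G1/S and G2/M genes was also weighed. The list medians differed by 0.43 on the log2 scale, whereas the highest of 10000 random list pairs matched on expression, exonic length and GC content reached 0.11 (percentile 100), which argues against length and GC content as the cause. A single scaling factor per library cannot alter this difference. With 1 library per group, an effect of the transfected MZF1-AS1 cannot be told apart from the separate growth of each culture.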
